A study of Mus musculus with 36 samples.

How the data were processed

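Poly(A) RNA of the mouse macrophage-like line J774.1 was measured on 36 Affymetrix arrays, 3 in each of 12 groups. The groups were made up of 3 RNA pools, each from intact cells and from cells given 100 ng/ml of Escherichia coli lipopolysaccharide (LPS) for 1, 2 or 4 h. Per the labels' protocols, cells were lysed in 0.5% NP-40 and the post-mitochondrial supernatant was spun through a 15 to 50% sucrose gradient that was divided into 20 fractions from the top. Fractions 11 to 20 were pooled as polysomes and fractions 1 to 5 as free messenger ribonucleoprotein (mRNP), and total cellular RNA was taken from cells that were not fractionated. Poly(A) RNA was selected and labelled with biotin by a one-cycle protocol, per the labels' protocols. Labels and time points were copied from the submitters' descriptions, and every array was assigned to a group by its title.

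The value table deposited by the authors holds one linear intensity per probe set and array, the MAS5 signal of the GCOS software named in the submitters' processing notes. Software versions and the settings of detection calls are not given in the sources used here. The trimmed mean of each array's 45101 intensities, with 2% removed from each end, was 500 in the deposited table. This scaling gives each pool the same trimmed mean signal, so a change in the amount of mRNA in a pool cannot be seen. A rise of many transcripts within the range kept lowers the others. Lists of probe sets that the authors deposited as changed or as translationally regulated carry no values per sample, and were used only for a count of shared calls. Their legends give a fold and an n = 3 test whose name is not stated.

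Of the 45101 probe sets, 64 controls were left out of the tests. A table of the platform's annotation gave 1 gene symbol for 34945 of the other 45037, several for 932 and none for 9160. The 34945 named 18193 genes, and looking these up by Entrez number changed 0 symbols. No gene is named from a probe set with several symbols. Different probe sets of a gene can differ, so gene lists and named genes used the probe set with the highest mean signal over the arrays of the fit. Median changes of the other probe sets are given where they went another way than a called change, or where 1 of them was itself called the other way.

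Intensities were scaled again to a trimmed mean of 500, 32 was added, and log2 was taken, so changes of dim probe sets are understated. Probe sets with a signal of at least 100 on at least 3 arrays of a fit were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend. The 12 total RNA arrays were fitted together (20026 probe sets, 10182 genes), as were the 24 gradient arrays (28932 probe sets, 14011 genes). Each contrast was adjusted by the method of Benjamini and Hochberg, and a probe set counted as called at an adjusted p under 0.05. The 14 planned contrasts compared each LPS time with intact cells in each pool and 4 h with 1 h in total RNA, asked whether the polysome to free mRNP ratio differed from that of intact cells (the polysome shift, an interaction term), and compared polysomes with free mRNP in intact cells. All changes are log2 differences ± standard error (SE), with 3 arrays per group.

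The groups, contrasts, tests, alternatives, 29 gene lists and the rule for naming genes were fixed before the data were examined. The rule takes, in each contrast, the 5 largest rises and falls among called probe sets whose 3 arrays of one group lie above all 3 of the other. For the shift there was no such condition on single arrays, and for polysomes against free mRNP 10 of each were taken. Up to 4 members of each described list with the largest change were added, along with Tnf, Il6, Il1b, Nfkbia, Fth1 and Actb. The lists covered inflammatory cytokines and chemokines, the NF-kB pathway with its feedback inhibitors, immediate-early genes, interferon-stimulated genes, macrophage effectors and receptors, macrophage identity genes, cytosolic ribosomal proteins, other mRNAs with a terminal oligopyrimidine tract (TOP) and elongation factors, translation initiation factors, nuclear-encoded oxidative phosphorylation subunits, proteasome subunits, iron handling, genes regulated by upstream open reading frames (uORFs) and the integrated stress response, endoplasmic reticulum chaperones, heat shock proteins, lysosome and phagosome, NRF2 and antioxidant genes, cholesterol synthesis and uptake, cell cycle and DNA replication, glycolysis and HIF targets, RNA-binding regulators of mRNA decay, zinc-finger KRAB and Polycomb regulators, replication-dependent histones, nuclear noncoding RNAs, and markers of fibroblasts, B and T lymphocytes, epithelium, neutrophils and mast cells, and erythroid cells. Lists with at least 5 measured members were tested with camera in limma, at a preset inter-gene correlation of 0.01 and again with an estimated one. Calls adjusted over the list alone are given beside those over all probe sets.

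The steps were tested on data simulated from the real means and spreads, with 100 probe sets changed by 1 and 100 by 2 (log2). For total RNA at 1 h, 86 and 98 were recovered, with 12 false calls among 19538 unchanged probe sets. For polysomes at 1 h they were 23 and 53, with 2 false calls among 26781. For free mRNP at 1 h they were 30 and 60, with 140 false calls among 26839, because the fit of both gradient pools takes one spread for both while free mRNP arrays vary more. For the polysome shift at 1 h, 7 and 33 were recovered with 3 false calls. Fits to the 12 arrays of a pool and with an array weight per pool were therefore added after seeing the data. The first gave 3 false calls among 25699 for free mRNP at 1 h while recovering 14 and 40, and the second gave 11 and recovered 10 and 40. The planned fit remains the one reported, and for free mRNP the added values are given for counts of calls, for lists compared with intact cells, and for a named gene where they ended its call. A list shifted by 0.5 was called in all 6 simulated contrasts, and 0 of 20 unchanged lists was. Gene correlation was not simulated.

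Also after seeing the data, 5 contrasts were added, in a fit of all 36 arrays (30051 probe sets, 14184 genes) for those that cross pools: 4 h against 2 h in polysomes and in the shift, and the change in free mRNP against the change in total RNA at each time. They were added because control probe sets for a spiked-in RNA divide the arrays into 2 sets that do not follow the pools or times alone, as described with the data. Alternatives tried for each result were an offset of 100, a floor of 16 with no offset, a filter of 250 or none, quantile normalization within each pool, scaling to the median of probe sets that pass the filter, eBayes without the trend, other choices of arrays in the fit, the replicate number as a block, total RNA in place of free mRNP for the shift, and leaving out each array. Arrays carry no depth, and their number limits the precision. The columns used hold 0 columns of another series. Nothing is printed from genome coordinates, since probe sets were used by name only.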

Results

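J774.1 is a mouse macrophage-like line, and LPS is the outer-membrane glycolipid of Gram-negative bacteria that macrophages sense through Toll-like receptors. The series measured poly(A) RNA in 3 pools, namely total cellular RNA, polysomes, where mRNAs carry several ribosomes, and free mRNP, the light part of the gradient where mRNAs carry few or none. Each pool was taken from intact cells and after 1, 2 and 4 h of LPS, with 3 arrays in each of the 12 groups. The design allows the question of which mRNAs changed in amount after LPS and which moved between polysomes and free mRNP. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

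Between 17626 and 19280 probe sets per array had a signal of at least 100 in total RNA, 15010 to 16804 in polysomes and 18387 to 24098 in free mRNP. The lowest and highest correlations of log2 signals between arrays of a group were 0.981 and 0.987 in total RNA, 0.976 and 0.984 in polysomes, and 0.893 and 0.941 in free mRNP, whose values are the least precise. Free mRNP also stood apart in its controls. The ratio of the 5' to the 3' control probe set of Actb, a sign of transcript integrity, averaged 0.368 in free mRNP of intact cells and 0.363, 0.232 and 0.262 after 1, 2 and 4 h. In polysomes it lay between 0.803 and 0.879 as a group mean, and in total RNA between 0.715 and 0.803. The ratio of 2 probe sets for dap, a bacterial RNA spiked into each sample, lay between 0.635 and 0.971 on 18 arrays, those of total RNA and of polysomes from intact and 1 h cells. It lay between 1.59 and 2.72 on the other 18, those of free mRNP and of polysomes at 2 and 4 h. These 2 sets of arrays were found after the data were seen. Within total RNA, within free mRNP and between polysomes at 1 h and intact cells, both sides of a comparison lie in one set. For polysomes at 2 and 4 h against intact cells, for the shift at those times and for polysomes against free mRNP in intact cells, array set and group cannot be told apart.

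**Figure D1:**
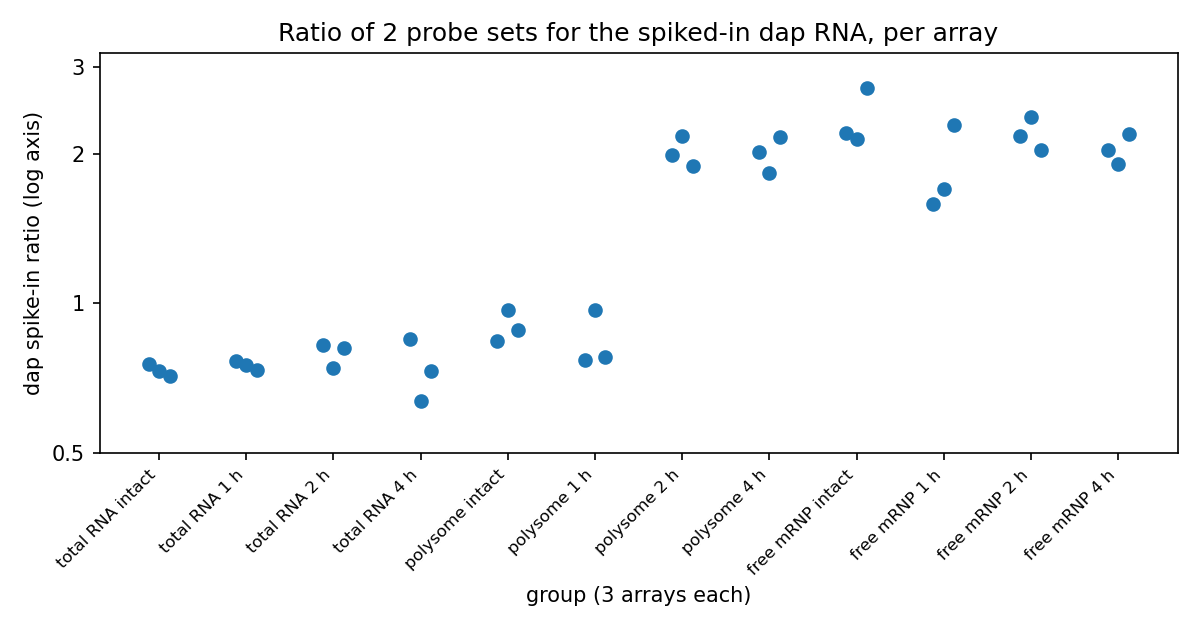
Ratio of 2 control probe sets for the spiked-in dap RNA (vertical axis, no unit), one point per array, by group along the horizontal axis, with 3 arrays per group. Values lie at 0.971 or below for total RNA and for polysomes of intact and 1 h cells, and at 1.59 or above for the other 18 arrays.

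In total RNA at 1 h of LPS the largest rises were those of inflammatory transcripts. Cxcl10, a chemokine for T cells, rose most (6.70 ± 0.11 on the log2 scale, SE, n = 3 per group; limma adjusted p = 5.9e-15). Its signal in intact cells was under 100, and the offset of 32 understates changes from such signals. Acod1, which makes the antibacterial metabolite itaconate, rose by 6.0 ± 0.17, the cytokines Il1b and Il6 by 5.67 ± 0.08 and 5.24 ± 0.13, and Ccrl2, an atypical chemoattractant receptor, by 4.72 ± 0.13. Tnf, a cytokine already present in intact cells at a signal of 2195 ± 288 (SD, n = 3), rose by 3.36 ± 0.09. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, rose by 1.12 ± 0.08. The largest falls were in the transcript 9930012K11Rik (-2.35 ± 0.24), in Dusp6 (-2.23 ± 0.10), a phosphatase that inactivates ERK, in Fsd1 (-2.0 ± 0.23) and in the transcription factors Klf10 (-1.75 ± 0.17) and Hhex (-1.72 ± 0.09). Fth1, the ferritin heavy chain, and Actb, a cytoskeletal actin, were not called (both 0.14, limma adjusted p = 0.43).

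List tests by camera are given with further p-values where an estimated correlation ended the call, or where quantile normalization or the use of all probe sets of a gene changed it. Of the inflammatory cytokines and chemokines, 22 of 24 rose (22 adjusted over the list alone), including the growth factor Csf2 (3.83 ± 0.16; camera adjusted p = 4.5e-54). Of the NF-kB pathway and its feedback inhibitors, 21 of 23 rose (22 adjusted over the list alone), led by Tnfaip3 (4.29 ± 0.07), Socs3 (3.98 ± 0.15), Traf1 (3.68 ± 0.11) and Nfkbiz (2.69 ± 0.09), all of them regulators of NF-kB or cytokine signals (camera adjusted p = 3.7e-49). Of immediate-early genes, 24 of 32 rose and 1 fell (26 and 1 adjusted over the list alone), with Nr4a1 (4.15 ± 0.20), Gadd45b (3.72 ± 0.09) and Junb (3.30 ± 0.11) the highest (camera adjusted p = 2.6e-44). Of macrophage effectors, 20 of 27 rose (21 adjusted over the list alone), among them the prostaglandin synthase Ptgs2 (4.18 ± 0.09) and the surface protein Cd83 (4.02 ± 0.10; camera adjusted p = 4.6e-38). Of the list of uORF-regulated and stress-response genes, 6 of 26 rose (10 adjusted over the list alone), led by the phosphatase regulator Ppp1r15a (2.76 ± 0.13; camera adjusted p = 9.4e-12). Zfp36 (3.01 ± 0.11) and Btg2 (2.17 ± 0.12), which promote mRNA decay, and the histone demethylase Kdm6b (2.73 ± 0.13) also rose. Their lists did not move as a whole. Of the RNA-binding regulators, 4 of 30 rose and 1 fell (5 and 2 adjusted over the list alone) (camera adjusted p = 0.2, adjusted p = 0.035 over all probe sets). Of the KRAB and Polycomb regulators, 1 of 24 rose and 2 fell (2 and 3 adjusted over the list alone) (camera adjusted p = 0.63). Their medians were -0.06 and -0.02 against means of 0.09 and 0.05. Interferon-stimulated genes were split, as 7 of 35 rose and 4 fell (7 and 5 adjusted over the list alone), with Slfn2 (2.93 ± 0.12) the highest. Their median was -0.01 and their mean 0.14 (camera adjusted p = 0.049, adjusted p = 0.61 with an estimated correlation, 0.061 with quantile normalization and 0.15 over all probe sets).

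At an adjusted p under 0.05, limma called 1786 probe sets in total RNA at 1 h, 743 higher and 1043 lower (417 in a fit of all 36 arrays). With arrays scaled to the median of the probe sets that pass the filter the split turned to 921 higher and 622 lower, so the balance of directions rests on the scaling. Leaving out 1 array gave between 1039 (without intact array 1) and 1628 calls, with 1149 without intact array 3 and 1108 without 1 h array 1.

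At 2 and 4 h cytokine genes still led the rises in total RNA. At 2 h Cxcl10 stood at 7.52 ± 0.11, the T-cell chemokine Ccl5 at 7.48 ± 0.20, Acod1 at 6.95 ± 0.17, Il6 at 6.81 ± 0.13 and Il1b at 6.08 ± 0.08. At 4 h the largest rises were Ccl5 (7.92 ± 0.20, limma adjusted p = 4.7e-13), Il6 (7.74 ± 0.13), Cxcl10 (7.67 ± 0.11), Acod1 (6.94 ± 0.17) and Csf2 (6.84 ± 0.16). Dusp6 (-3.44 ± 0.10), Klf10 (-3.36 ± 0.17), Dusp7 (-3.11 ± 0.27), C130050O18Rik (-2.98 ± 0.18) and the RNA-decay factor Zfp36l2 (-3.38 ± 0.16) led the falls at 2 h. At 4 h they were Klf10 (-3.60 ± 0.17), Zfp36l2 (-3.59 ± 0.16), the fractalkine receptor Cx3cr1 (-3.27 ± 0.27), the G1 cyclin Ccnd1 (-3.20 ± 0.09) and 2900026A02Rik (-3.17 ± 0.18). Tnf stayed high (3.15 ± 0.09 and 3.17 ± 0.09), as did Nfkbia (1.34 ± 0.08 and 1.16 ± 0.08).

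Of 35 interferon-stimulated genes measured, 20 rose and 3 fell at 2 h (22 and 4 adjusted over the list alone; camera adjusted p = 1.5e-09, adjusted p = 0.15 with an estimated correlation) and 32 rose and 1 fell at 4 h (32 and 2 adjusted over the list alone; camera adjusted p = 4.8e-26). At 4 h the antiviral genes Ifit1 (6.45 ± 0.22), Rsad2 (6.34 ± 0.18) and Oasl1 (5.73 ± 0.12) led, with Usp18 (5.65 ± 0.22), which removes ISG15 from proteins. Among cell cycle and DNA replication genes, 24 of 40 fell (25 adjusted over the list alone) at 2 h (camera adjusted p = 2.9e-05, adjusted p = 0.12 with an estimated correlation). At 4 h, 34 of 40 fell (35 adjusted over the list alone) (camera adjusted p = 2e-11), with Cdc6 (-2.85 ± 0.09), E2f2 (-2.77 ± 0.10) and Ccne2 (-2.30 ± 0.17) beside Ccnd1. Cytokines stayed high, as 22 of 24 rose at 2 h (22 adjusted over the list alone, camera adjusted p = 7.5e-29). At 4 h, 23 rose (23, camera adjusted p = 9.4e-29). Effectors did likewise, as 25 of 27 rose at 2 h (25, camera adjusted p = 1.2e-26). At 4 h, 25 rose (25, camera adjusted p = 8.9e-24). Among them were the acute-phase protein Saa3 (5.09 ± 0.24 at 2 h) and the scavenger receptor Marco (3.86 ± 0.26). NF-kB pathway genes that fell appeared at 2 h, when 21 of 23 rose and 2 fell (21 and 2, camera adjusted p = 2.1e-26). At 4 h 21 rose and 2 fell (21 and 2, camera adjusted p = 2.2e-20). Immediate-early genes spread in both directions, as 19 of 32 rose and 7 fell (20 and 8 adjusted over the list alone) at 2 h (camera adjusted p = 1.6e-06, adjusted p = 0.066 with an estimated correlation). At 4 h, 18 rose and 5 fell (18 and 6, camera adjusted p = 1.7e-07). Of the uORF and stress list, 21 of 26 rose and 1 fell at 2 h (22 and 1, camera adjusted p = 1.6e-12). At 4 h, 19 rose and 2 fell (20 and 2, camera adjusted p = 2.4e-10). Macrophage identity genes went both ways at 4 h, when 7 of 29 rose and 12 fell (7 and 12 adjusted over the list alone) (camera adjusted p = 0.56). Here Cx3cr1 was down with the Fc receptor Fcgr3 (-1.68 ± 0.11), and the F4/80 antigen Adgre1 (2.56 ± 0.11) was up.

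Several housekeeping lists were called by camera at 2 or 4 h, but none of those calls held with an estimated correlation or with quantile normalization. Of cytosolic ribosomal proteins, 27 of 43 rose and 1 fell (34 and 2 adjusted over the list alone) at 2 h (camera adjusted p = 1.2e-08, adjusted p = 0.52 with an estimated correlation and 0.65 with quantile normalization). At 4 h, 16 of 43 rose and 2 fell (20 and 2 adjusted over the list alone) (camera adjusted p = 1.5e-05, adjusted p = 0.56 with an estimated correlation and 0.85 with quantile normalization). Of proteasome subunits, 8 of 32 rose and 2 fell (8 and 2 adjusted over the list alone) at 2 h (camera adjusted p = 0.017, adjusted p = 0.54 with an estimated correlation and 0.65 with quantile normalization). At 4 h, 6 of 32 rose and 0 fell (3 and 0 adjusted over the list alone) (camera adjusted p = 0.006, adjusted p = 0.56 with an estimated correlation and 0.4 with quantile normalization). Initiation factors stood at 12 of 32 rose and 5 fell (13 and 5 adjusted over the list alone) at 4 h (camera adjusted p = 0.016, adjusted p = 0.27 with an estimated correlation and 0.15 with quantile normalization), with the RNA-activated kinase Eif2ak2 up (1.41 ± 0.12) and the eIF4E kinase Mknk2 down (-1.28 ± 0.09). Of heat shock proteins 8 of 18 rose and 2 fell (10 and 2 adjusted over the list alone) at 4 h (camera adjusted p = 0.024, adjusted p = 0.48 with an estimated correlation and 0.46 with quantile normalization). Of glycolysis genes 7 of 19 rose and 3 fell (7 and 3 adjusted over the list alone) at 2 h (camera adjusted p = 0.03, adjusted p = 0.35 with an estimated correlation and 0.35 with quantile normalization). Of lysosome genes 3 of 29 rose and 11 fell (3 and 13 adjusted over the list alone) at 4 h (camera adjusted p = 0.5, adjusted p = 0.025 with quantile normalization). Of iron handling genes 5 of 13 rose and 3 fell (5 and 3 adjusted over the list alone) at 4 h (camera adjusted p = 0.089, adjusted p = 3.5e-05 over all probe sets). The siderophore-binding Lcn2 (4.24 ± 0.11) and the ferroxidase Cp (3.98 ± 0.48) rose and the iron exporter Slc40a1 fell (-1.30 ± 0.12). Fth1 at 2 h was 0.32 ± 0.09 (limma adjusted p = 0.017) but -0.01 with quantile normalization. It was not called without intact array 3 or 2 h array 1 (adjusted p = 0.07 and 0.061). At 4 h Fth1 (0.27 ± 0.09) and Actb (0.25 ± 0.09) were called by limma, but not with quantile normalization (0.02 and 0.01). Neither was called without 4 h array 1 (adjusted p = 0.13 and 0.17) or intact array 1 (0.07 and 0.1) or 3 (0.12 and 0.14), and Actb was not called without 4 h array 2 (0.059). Actb at 2 h stood at 0.42 ± 0.09.

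limma called 6891 probe sets at 2 h, 2655 higher and 4236 lower, and 8005 at 4 h, 3038 higher and 4967 lower (1751 and 3040 in a fit of all 36 arrays). With scaling to the median of filtered probe sets these splits were 3827 to 2748 and 4422 to 3589.

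Between 1 and 4 h, a comparison that leaves out the intact cells, the antiviral genes Rsad2 (5.96 ± 0.18, limma adjusted p = 3.7e-11), Usp18 (5.71 ± 0.22), Ifit1 (5.67 ± 0.22), Cmpk2 (5.43 ± 0.28) and Rtp4 (5.38 ± 0.24) rose most in total RNA. The urokinase gene Plau (-3.32 ± 0.23), Cx3cr1 (-2.99 ± 0.27), Ccnd1 (-2.99 ± 0.09), the phosphatase Dusp1 (-2.85 ± 0.09) and 2900026A02Rik (-2.80 ± 0.18) fell most. Of interferon-stimulated genes, 32 of 35 rose and 1 fell (32 and 1 adjusted over the list alone) (camera adjusted p = 7.9e-27). Of cell cycle genes, 1 of 40 rose and 28 fell (1 and 29 adjusted over the list alone) (camera adjusted p = 5.5e-13). Of immediate-early genes, 1 of 32 rose and 18 fell (1 and 18 adjusted over the list alone) (camera adjusted p = 9.8e-06, adjusted p = 0.086 with an estimated correlation). Of cytokines, 16 of 24 rose and 2 fell (16 and 2 adjusted over the list alone) (camera adjusted p = 4e-09, adjusted p = 0.076 with an estimated correlation), led by Ccl5 (4.48 ± 0.20), Csf3 (3.49 ± 0.18) and Il12b (3.16 ± 0.17). Of effectors, 17 of 27 rose and 4 fell (17 and 4 adjusted over the list alone) (camera adjusted p = 5.7e-08). Il6 rose further (2.5 ± 0.13), as did Il1b by a little (0.49 ± 0.08). Tnf (-0.19 ± 0.09, adjusted p = 0.13) and Nfkbia (0.03 ± 0.08, adjusted p = 0.78) were not called in limma. The 4 other probe sets of Nfkbia had a median of -0.21, and 1 of them fell. Cholesterol synthesis genes had 0 rises and 10 falls (0 and 13 adjusted over the list alone; camera adjusted p = 0.0093, adjusted p = 0.36 with an estimated correlation). Endoplasmic reticulum chaperones had 0 rises and 9 falls among 23 (1 and 10 adjusted over the list alone; camera adjusted p = 0.023, adjusted p = 0.57 with an estimated correlation). In all 6220 probe sets were called by limma, 2741 higher and 3479 lower at 4 h (1804 in that fit).

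**Figure D2:**
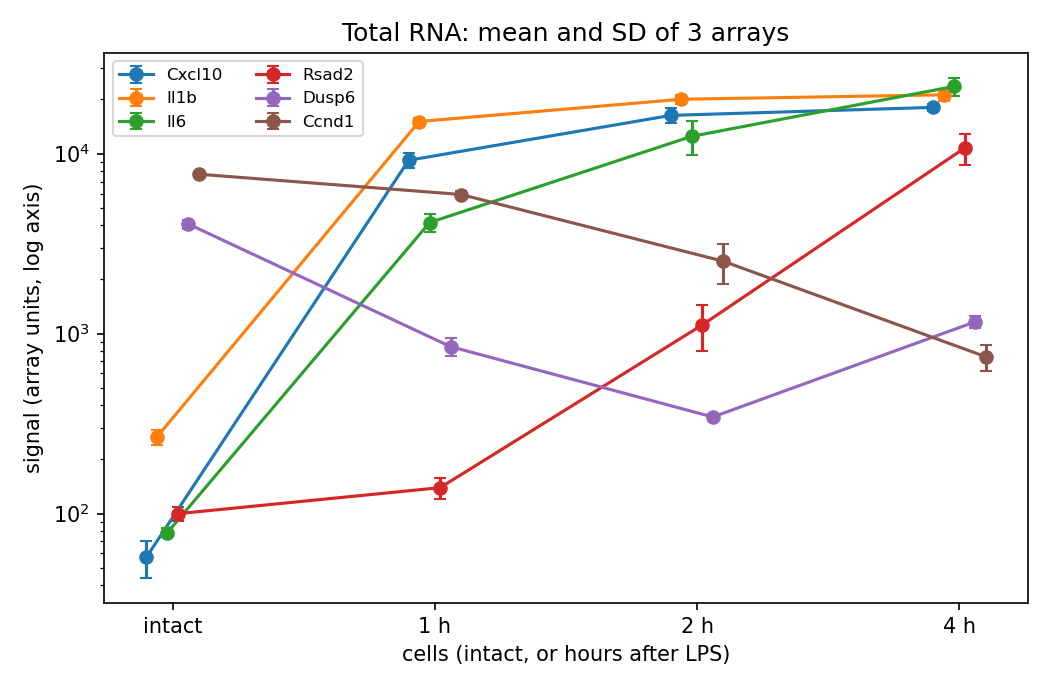
Signals in total RNA (vertical log axis, linear MAS5 signal) of Cxcl10, Il1b, Il6, Rsad2, Dusp6 and Ccnd1 by hours of LPS (horizontal axis), as mean and SD of 3 arrays, with intact cells at the left. Cxcl10 went from 57.23 ± 13.2 in intact cells to 9190 ± 870 at 1 h, while Rsad2 rose by 5.96 and Ccnd1 fell by 2.99 (log2) from 1 to 4 h.

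In polysomes at 1 h cytokine and early-response transcripts rose, and Tnf was among the 5 largest rises. Cxcl10 rose by 6.06 ± 0.29, Il6 by 5.73 ± 0.34, Acod1 by 5.66 ± 0.20, Il1b by 5.17 ± 0.21 and Tnf by 5.01 ± 0.18 (limma adjusted p = 6.7e-19), against 3.36 for Tnf in total RNA. Nfkbia rose by 0.85 ± 0.15. The largest falls were 9930012K11Rik (-2.63 ± 0.39), Txnip (-2.10 ± 0.19), an inhibitor of thioredoxin and glucose uptake, the G-protein regulator Rgs2 (-2.06 ± 0.26), and the zinc-finger genes Zfp688 (-2.07 ± 0.37) and Zbtb14 (-1.99 ± 0.30). Fth1 (-0.24 ± 0.20) and Actb (0.08 ± 0.24, 0.00 with quantile normalization) were not called. Of cytokines, 17 of 28 rose (20 adjusted over the list alone, camera adjusted p = 9.7e-74). Of NF-kB pathway genes, 15 of 23 rose (16, camera adjusted p = 7.5e-56). Of immediate-early genes, 22 of 34 rose (27, camera adjusted p = 7.8e-75). Of effectors, 14 of 33 rose (15, camera adjusted p = 7.9e-33). Tnfaip3 (4.95 ± 0.20), Nfkbiz (3.78 ± 0.14), Nr4a1 (4.05 ± 0.40), the kinase Plk2 (3.64 ± 0.26) and Ptgs2 (4.78 ± 0.22) led these lists. Of oxidative phosphorylation subunits, 0 of 74 rose and 4 fell (0 and 16 adjusted over the list alone) (camera adjusted p = 2.3e-09, adjusted p = 0.36 with an estimated correlation). Of the RNA-binding regulators, 3 of 30 rose and 0 fell (4 and 1 adjusted over the list alone) (camera adjusted p = 0.025, adjusted p = 0.36 with an estimated correlation), led by Zfp36 (3.65 ± 0.17) and Btg2 (2.56 ± 0.30). limma called 455 probe sets, 281 higher and 174 lower. Leaving out 1 array gave 286 (without 1 h array 1) to 460, and the count was 1035 with the 12 polysome arrays alone and 1479 with array weights.

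At 2 and 4 h cytokines led the rises in polysomes. The largest rises at 4 h were Ccl5 (8.42 ± 0.32, limma adjusted p = 1.9e-18), Il6 (8.01 ± 0.34), Csf2 (7.92 ± 0.29), Cxcl10 (7.78 ± 0.29) and Il12b (7.39 ± 0.46), a subunit of interleukins 12 and 23. At 2 h they were Cxcl10 (7.65 ± 0.29), Acod1 (7.10 ± 0.20), Il6 (7.01 ± 0.34), Ccl5 (6.81 ± 0.32) and Csf2 (6.10 ± 0.29). Falls were led at 2 h by Dusp7 (-3.79 ± 0.32), Dusp6 (-3.70 ± 0.21), Klf10 (-3.54 ± 0.42), Ankrd10 (-3.31 ± 0.35) and Zfp36l2 (-3.29 ± 0.25). At 4 h they were led by Zfp36l2 (-4.54 ± 0.25), Klf10 (-4.08 ± 0.42), Klhl2 (-3.82 ± 0.40), Plau (-3.75 ± 0.28) and C130050O18Rik (-3.55 ± 0.41). Tnf stood at 4.84 ± 0.18 and 5.18 ± 0.18, Il1b at 5.28 ± 0.21 and 5.48 ± 0.21, and Nfkbia at 0.67 ± 0.15 and 0.70 ± 0.15. Fth1 rose (0.72 ± 0.20 and 0.89 ± 0.20), but its other probe set changed by -0.11 and 0.07. At 2 h limma did not call it without intact array 1 or 2 h array 2 or 3 (adjusted p = 0.06, 0.11 and 0.074). Actb was not called (0.19 ± 0.24 and 0.23 ± 0.24), while its other probe set fell by 1.51 at both times. Of cytokines, 21 of 28 rose (21 adjusted over the list alone) at 2 h (camera adjusted p = 3.1e-43). At 4 h, 23 of 28 rose (24 adjusted over the list alone) (camera adjusted p = 1.6e-41). Of NF-kB pathway genes, 21 of 23 rose (21 adjusted over the list alone) at 2 h (camera adjusted p = 3.1e-43). At 4 h, 19 of 23 rose (20 adjusted over the list alone) (camera adjusted p = 1.4e-33). Of effectors, 21 of 33 rose and 0 fell (22 and 1 adjusted over the list alone) at 2 h (camera adjusted p = 1.9e-26). At 4 h, 22 of 33 rose (24 adjusted over the list alone) (camera adjusted p = 6.1e-29), with Saa3 (7.13 ± 0.35) and Marco (6.96 ± 0.40) the highest. Interferon-stimulated genes were split at 2 h, when 8 of 34 rose and 3 fell (8 and 6 adjusted over the list alone), with a median of -0.13 and a mean of 0.33 (camera adjusted p = 0.17). At 4 h, 28 of 34 rose and 0 fell (29 and 1 adjusted over the list alone) (camera adjusted p = 3.5e-31). Of cell cycle genes, 1 of 40 rose and 20 fell (1 and 20 adjusted over the list alone) at 4 h (camera adjusted p = 6.3e-09). Of NRF2 and antioxidant genes, 8 of 20 rose and 2 fell (9 and 2 adjusted over the list alone) at 2 h (camera adjusted p = 0.00032), led by the cystine transporter Slc7a11 (2.99 ± 0.27) and the metallothionein Mt2 (2.18 ± 0.26). limma called 3433 probe sets at 2 h, 1379 higher and 2054 lower, and 4852 at 4 h, 1921 higher and 2931 lower. The counts were 6831 and 8261 with the 12 polysome arrays alone and 6905 and 8471 with array weights. With scaling to the median of filtered probe sets 78.9% of 4640 and 74.1% of 5377 calls were rises. Array set and time cannot be told apart here.

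Between 2 and 4 h, where all polysome arrays lie in one set, a contrast added after seeing the data, Usp18 (5.33 ± 0.39, limma adjusted p = 2.1e-10), Rsad2 (4.71 ± 0.35), Rtp4 (4.71 ± 0.34), Ifit1 (4.12 ± 0.33) and Slfn8 (3.79 ± 0.25) rose most. Of interferon-stimulated genes, 26 of 34 rose (29 adjusted over the list alone, camera adjusted p = 8.3e-72). Of cytokines, 7 of 28 rose and 0 fell (12 and 1, camera adjusted p = 2.5e-09). Of cell cycle genes, 1 of 40 rose and 9 fell (2 and 15, camera adjusted p = 1.2e-10). Of oxidative phosphorylation subunits 0 of 74 was called, with the list lower (camera adjusted p = 3.3e-07, 0.53 with an estimated correlation). Ccnd1 (-2.34 ± 0.21), the GTPase regulator Rasa3 (-2.34 ± 0.35) and Cd83 (-1.98 ± 0.16) fell, as did 2900026A02Rik (-2.75 ± 0.38) and Hdac9 (-2.19 ± 0.44), whose other probe sets changed by 0.18 and 0.45. Of iron handling genes, 2 of 14 rose and 0 fell (3 and 0 adjusted over the list alone) (camera adjusted p = 0.0057, adjusted p = 0.065 with an estimated correlation), namely Cp (2.88 ± 0.57) and Lcn2 (1.5 ± 0.29). limma called 570 probe sets, 253 higher and 317 lower. The count was 1678 with the 12 polysome arrays alone, 1999 with array weights, 2198 with the 2 groups alone and 353 without the trend. Leaving out 1 array gave 266 to 472 calls, with 266 and 360 without 2 h arrays 3 and 2, and 331 and 316 without 4 h arrays 1 and 2.

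Free mRNP gained inflammatory mRNAs as well. At 1 h Cxcl10 (5.53 ± 0.29), the neutrophil chemokine Cxcl2 (5.21 ± 0.18), Acod1 (4.95 ± 0.20), Ptgs2 (4.81 ± 0.22) and Il1b (4.51 ± 0.21) rose most. Nfkbia rose by 2.60 ± 0.15 (limma adjusted p = 2.1e-13) against 0.85 in polysomes. Tnf rose by 2.24 ± 0.18. At 2 h the largest rises were Ccl5 (8.11 ± 0.32), Cxcl10 (7.67 ± 0.29), Il6 (7.24 ± 0.34), Acod1 (7.12 ± 0.20) and Il1b (5.80 ± 0.21). At 4 h they were Ccl5 (9.52 ± 0.32), Il6 (8.37 ± 0.34), Cxcl10 (8.22 ± 0.29), Saa3 (7.97 ± 0.35) and Acod1 (7.60 ± 0.20). Dusp7 (-4.17 ± 0.32), the glycosyltransferase B3gnt7 (-3.27 ± 0.35), Dusp6 (-3.21 ± 0.21) and C130050O18Rik (-2.96 ± 0.41) fell at 2 h. Rab3il1 (-4.19 ± 0.20), Ccnd1 (-3.92 ± 0.21), Dusp7 (-3.91 ± 0.32) and C130050O18Rik (-3.90 ± 0.41) fell at 4 h. Zfp36l2 fell by more still (-4.21 ± 0.25 and -4.52 ± 0.25), but its other probe set changed by 0.15 and 0.74. Tnf stood at 1.91 ± 0.18 and 2.29 ± 0.18 and Nfkbia at 2.5 ± 0.15 and 2.64 ± 0.15. Fth1 (-0.38 ± 0.20 and -0.48 ± 0.20) and Actb (-0.44 ± 0.24 and -0.41 ± 0.24) were not called. The falls at 1 h were less secure. Slc25a2 (-2.38 ± 0.39), Serpinh1 (-2.38 ± 0.38) and Il1f5 (-2.33 ± 0.40) were called with the 12 free mRNP arrays alone as well (limma adjusted p = 0.039, 0.027 and 0.016). Zfp157 (-2.31 ± 0.47) and Mall (-2.23 ± 0.47) were not (limma adjusted p = 0.071 and 0.12).

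By list, of cytokines 17 of 28 rose and 0 fell (19 and 1 adjusted over the list alone) at 1 h (camera adjusted p = 2.7e-38), 21 of 28 rose and 2 fell (21 and 3 adjusted over the list alone) at 2 h (camera adjusted p = 2.5e-32). At 4 h, 22 of 28 rose and 1 fell (23 and 1 adjusted over the list alone) (camera adjusted p = 8.2e-40). Of immediate-early genes, 21 of 34 rose (24 adjusted over the list alone) at 1 h (camera adjusted p = 1.1e-45). Of NF-kB pathway genes, 12 of 23 rose (16 adjusted over the list alone) at 1 h (camera adjusted p = 5e-34), and of effectors 13 of 33 rose (15 adjusted over the list alone) (camera adjusted p = 1.9e-19). Of interferon-stimulated genes, 8 of 34 rose and 5 fell (10 and 7 adjusted over the list alone) at 2 h (camera adjusted p = 0.032, adjusted p = 0.51 with an estimated correlation). At 4 h, 26 of 34 rose and 1 fell (26 and 1 adjusted over the list alone) (camera adjusted p = 1.1e-26), led by Rsad2 (5.80 ± 0.35) and Oasl1 (5.37 ± 0.31). Of cell cycle genes, 2 of 40 rose and 20 fell (2 and 23 adjusted over the list alone) at 4 h (camera adjusted p = 3.1e-07). Of proteasome subunits, 11 of 32 rose (14 adjusted over the list alone) at 2 h (camera adjusted p = 1.7e-09, adjusted p = 0.088 with quantile normalization). Of oxidative phosphorylation subunits, 23 of 74 rose and 1 fell (39 and 1 adjusted over the list alone) at 2 h (camera adjusted p = 2.9e-14, adjusted p = 0.16 with an estimated correlation and 0.087 with quantile normalization). Of NRF2 and antioxidant genes, 5 of 20 rose and 1 fell (5 and 1 adjusted over the list alone) at 4 h (camera adjusted p = 0.00091), led by Slc7a11 (3.99 ± 0.27) and the mitochondrial dismutase Sod2 (2.89 ± 0.14). With the 12 free mRNP arrays alone the rises and falls were 15 and 0, 20 and 1, and 22 and 0 for cytokines at 1, 2 and 4 h. At 1 h they were 18 and 0 for immediate-early genes, 10 and 0 for the NF-kB pathway and 12 and 0 for effectors. They were 6 and 4 at 2 h and 23 and 1 at 4 h for interferon-stimulated genes, 1 and 17 at 4 h for cell cycle genes, and 5 and 1 at 4 h for NRF2 genes. They were 7 and 0 at 2 h for proteasome subunits, 4 and 0 at 2 h for oxidative phosphorylation and 13 and 1 at 4 h for the uORF and stress list.

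Calls in free mRNP by limma were 857 at 1 h (438 higher, 419 lower), 4361 at 2 h (1339 and 3022) and 4852 at 4 h (1556 and 3296). They were 264, 1928 and 2608 with the 12 free mRNP arrays alone and 183, 1310 and 2076 with array weights, which both gave fewer false calls on simulated data at 1 h. The median of all tested probe sets was -0.107, -0.234 and -0.233, to which single changes can be set. With quantile normalization 64.8% of 802, 50.2% of 2853 and 48.3% of 3909 calls were rises. With median scaling they were 84.4% of 860, 81% of 3961 and 77.3% of 4545, so the surplus of falls depends on the scaling. At 1 h leaving out 1 array gave 553 (without intact array 2) to 1102 calls. The mean Actb 5' to 3' ratio of this pool was 0.368 and 0.363 in intact and 1 h cells and 0.232 and 0.262 at 2 and 4 h.

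The polysome shift asked whether an mRNA's balance between polysomes and free mRNP changed with LPS. At 1 h Tnf moved toward polysomes by 2.76 ± 0.25 (limma adjusted p = 1.3e-07). The same direction was taken by the growth factor Csf2 (2.93 ± 0.40), the nuclear NF-kB inhibitor Nfkbid (2.74 ± 0.38), the early-response gene Ier3 (2.18 ± 0.27) and the RNase Zc3h12a (1.63 ± 0.29). Nfkbia moved the other way, by -1.75 ± 0.22 (limma adjusted p = 5e-05), and the median of its 4 other probe sets was -0.79. Also toward free mRNP went Ccl5 (-2.11 ± 0.46), the mitochondrial ribosomal protein Mrps30 (-1.36 ± 0.24), Ilkap (-1.32 ± 0.21), whose other probe set changed by 0.89, and Mknk2 (-1.33 ± 0.29). Mean signals of Tnf went from 770.2 ± 127 to 25820 ± 4790 in polysomes and from 11250 ± 1660 to 53000 ± 2900 in free mRNP (SD, n = 3). Mean signals of Nfkbia went from 16260 ± 1400 to 29470 ± 4980 and from 6318 ± 1730 to 37600 ± 141. Mall (3.09 ± 0.66) and Reg1 (2.80 ± 0.61) were also among the largest rises. Neither they nor Mknk2 were called with array weights per pool (limma adjusted p = 0.062, 0.053 and 0.072). Ccl5 was not called without polysome intact array 1 (adjusted p = 0.13) nor without most other arrays. Il6 (1.53 ± 0.48), Il1b (0.67 ± 0.30), Fth1 (0.12 ± 0.29) and Actb (0.04 ± 0.34) were not called. With total RNA in place of free mRNP limma called 8 probe sets, and Nfkbia (-0.28), Csf2 (0.77), Nfkbid (1.63), Zc3h12a (0.47), Mrps30 (-0.51) and Ilkap (-0.42) were not among them.

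Tnf kept its place at 2 and 4 h (2.94 ± 0.25 and 2.89 ± 0.25), as did Nfkbia (-1.82 ± 0.22 and -1.94 ± 0.22), Csf2 (2.25 ± 0.40 and 2.07 ± 0.40), Nfkbid (2.46 ± 0.38 and 2.23 ± 0.38) and Ier3 (1.94 ± 0.27 and 2.33 ± 0.27). Of cytokines, 2 of 28 rose and 1 fell at 1 h (8 and 1 adjusted over the list alone). The list moved toward polysomes (camera adjusted p = 3.7e-07). Whether the higher median signal of intact free mRNP arrays makes rises there smaller was not tested. Of NF-kB pathway genes, 2 of 23 rose and 1 fell (4 and 1, camera adjusted p = 0.21). Of immediate-early genes, 1 of 34 rose and 0 fell (2 and 0, camera adjusted p = 0.0016, adjusted p = 0.16 with an estimated correlation and 0.074 over all probe sets). Of effectors, 0 of 33 was called in limma. Of oxidative phosphorylation subunits, 0 of 74 rose and 0 fell (0 and 6), with the list lower (camera adjusted p = 2.2e-08, adjusted p = 0.74 with an estimated correlation). limma called 47 probe sets at 1 h, 21 toward polysomes and 26 toward free mRNP. There were 2647 at an unadjusted p under 0.05, and a median of 0.106 over all. Median scaling gave 145 calls, 8.97% of them toward polysomes, and quantile normalization 70, 27.1% of them. Leaving out 1 array gave 22 to 66 calls, with 22, 24, 23 and 28 without polysome 1 h arrays 2 and 1 and intact arrays 1 and 3. It gave 25, 29 and 30 without free mRNP 1 h arrays 2 and 3 and intact array 2.

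**Figure D3:**
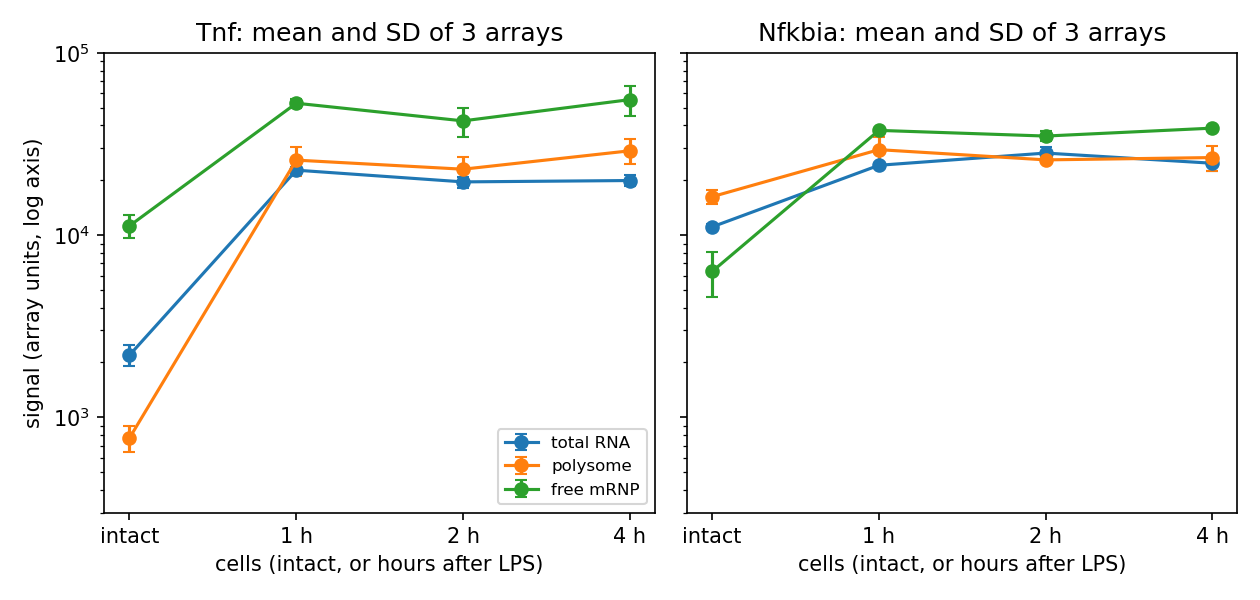
Signals of Tnf and Nfkbia (vertical log axis, linear MAS5 signal) in total RNA, polysomes and free mRNP by hours of LPS (horizontal axis), as mean and SD of 3 arrays, with intact cells at the left. Tnf rose by 5.01 in polysomes and 2.24 in free mRNP at 1 h, and Nfkbia by 0.85 and 2.60 (log2).

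At 2 and 4 h, when the Actb 5' to 3' ratio was also lower in free mRNP (0.232 and 0.262 against 0.368) and near level in polysomes (0.821 and 0.803 against 0.824), the largest shifts toward polysomes were those of Kdm6b (4.61 ± 0.61 and 4.13 ± 0.61), Il12b (4.19 ± 0.65 and 3.78 ± 0.65) and the splicing factor Nsrp1 (3.99 ± 0.75 and 3.31 ± 0.75). They were joined by Marco (3.34 ± 0.57) and Fhl3 (3.15 ± 0.75) at 2 h and by Apbb2 (2.97 ± 0.55) and Dtx3l (2.89 ± 0.38) at 4 h. Toward free mRNP went the kinase of deoxycytidine, Dck (-3.27 ± 0.38 and -3.22 ± 0.38), the spliceosome protein Rnpc3 (-3.26 ± 0.54 and -3.32 ± 0.54), and at 2 h Cyp20a1 (-3.12 ± 0.44), Wsb1 (-2.69 ± 0.40) and the lipid-transfer protein Pltp (-2.77 ± 0.79). limma did not call Pltp without array 1 of intact polysomes, array 3 of 2 h polysomes, or array 3 of intact or 2 h free mRNP (adjusted p = 0.1, 0.11, 0.091 and 0.094). Further shifts toward free mRNP were those of Aco1 (-3.15 ± 0.38), Klhl2 (-2.93 ± 0.57) and Ccne2 (-2.86 ± 0.52) at 4 h. Aco1, also known as iron regulatory protein, binds the mRNAs of Fth1 and of the transferrin receptor Tfrc. Its 2 other probe sets had a median of 0.00 at 4 h. Fth1 stood at 1.10 ± 0.29 and 1.37 ± 0.29 (limma adjusted p = 0.017 and 0.0032, other probe set -0.08 and 0.16). At 2 h it was not called without polysome 2 h array 2 or free mRNP intact array 3 (limma adjusted p = 0.062 and 0.051). Tfrc stood at 1.27 ± 0.21, with -0.04 for its other probe sets, and 1.56 ± 0.21. With total RNA in place of free mRNP neither was called, nor were Il12b (0.54 and 1.24), Nsrp1 (0.68 and 0.97) and Marco (0.43). Of iron handling genes, 2 of 14 rose and 1 fell (3 and 2 adjusted over the list alone) at 2 h (camera adjusted p = 0.98). At 4 h, 2 of 14 rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.89).

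Among TOP mRNAs other than ribosomal proteins, 3 of 18 rose (11 adjusted over the list alone) at 4 h (camera adjusted p = 0.00046, adjusted p = 0.68 with an estimated correlation and 0.62 over all probe sets), namely Eif4b (1.05 ± 0.21), Npm1 (1.01 ± 0.25) and Eef2 (1.06 ± 0.30). Eef2 was not called with quantile or median scaling. Of cytosolic ribosomal proteins, 5 of 43 rose and 1 fell (15 and 1 adjusted over the list alone) at 4 h (camera adjusted p = 0.00016, adjusted p = 0.86 with an estimated correlation and 0.96 with quantile normalization). With quantile normalization its direction turned, and 0 members were called with array weights. At 2 h, of ribosomal proteins 1 of 43 rose and 1 fell (3 and 1 adjusted over the list alone) (camera adjusted p = 0.044, adjusted p = 0.88 with an estimated correlation, 0.96 with quantile normalization and 0.19 over all probe sets). Of other TOP mRNAs 3 of 18 rose (5 adjusted over the list alone) (camera adjusted p = 0.044, adjusted p = 0.88 with an estimated correlation, 0.064 with quantile normalization and 0.7 over all probe sets). Of proteasome subunits 1 of 32 rose and 4 fell (1 and 5 adjusted over the list alone) (camera adjusted p = 0.044, adjusted p = 0.88 with an estimated correlation and 0.73 with quantile normalization). Of lysosome genes 1 of 29 rose and 5 fell (2 and 5 adjusted over the list alone) (camera adjusted p = 0.044, adjusted p = 0.88 with an estimated correlation, 0.54 with quantile normalization and 0.21 over all probe sets). Of cytokines, 7 of 28 rose and 1 fell (8 and 3 adjusted over the list alone) at 2 h (camera adjusted p = 0.044, adjusted p = 0.88 with an estimated correlation and 0.064 with quantile normalization). At 4 h, 5 of 28 rose and 1 fell (5 and 2 adjusted over the list alone) (camera adjusted p = 0.29). limma called 1952 probe sets at 2 h (1019 toward polysomes, 933 toward free mRNP) and 1738 at 4 h (832 and 906). They were 977 and 1032 with total RNA in place of free mRNP and 1226 and 1144 without the trend. Array set and time cannot be told apart in these 2 contrasts. Between 4 and 2 h, within one set and added after seeing the data, limma called 0 probe sets, with 1494 at an unadjusted p under 0.05, and 1 or 2 without 2 h or 4 h free mRNP array 1. NF-kB pathway genes were lower at 4 h as a list (camera adjusted p = 1e-04, adjusted p = 0.06 with an estimated correlation) and interferon-stimulated genes higher (camera adjusted p = 0.0015, adjusted p = 0.39 with an estimated correlation), with 0 members called in either list, over all probe sets or adjusted over the list alone. Leaving out 1 array moved the counts to 1236 (without polysome 2 h array 2) and 1293 (without polysome intact array 1) at 2 h, and to 1073 (without polysome intact array 1) and 1109 (without polysome 4 h array 3) at 4 h.

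In intact cells the pools differed in composition, and also in the Actb 5' to 3' ratio (0.824 in polysomes, 0.368 in free mRNP). As each pool is scaled to the same mean, values are relative to the rest of a pool. Of ribosomal proteins, 1 of 43 was higher in polysomes and 42 were lower (1 and 42 adjusted over the list alone; camera adjusted p = 6.4e-27, adjusted p = 0.22 with an estimated correlation), among them Rps27 (-4.32 ± 0.31) and Rpl41 (-4.26 ± 0.24). Of other TOP mRNAs 1 of 18 was higher and 16 were lower (1 and 16 adjusted over the list alone; camera adjusted p = 5.2e-08, adjusted p = 0.17 with an estimated correlation). Furthest toward free mRNP lay Smim27 (-7.06 ± 0.22, limma adjusted p = 3.5e-20), Pkig (-6.40 ± 0.24), Tmem134 (-6.23 ± 0.21), Bola3 (-6.0 ± 0.23), Serf1 (-5.87 ± 0.33) and the selenoprotein Selenow (-5.84 ± 0.27). With them lay the snoRNA host transcripts Snhg8 (-6.45 ± 0.27), Gas5 (-6.23 ± 0.20) and Snhg4 (-6.06 ± 0.21), and mitochondrially encoded ND5 (-6.14 ± 0.27). Furthest toward polysomes lay Ccar1 (4.87 ± 0.41), Ampd2 (4.57 ± 0.27), Gna13 (4.51 ± 0.44), Ubn1 (4.21 ± 0.38), the histidyl-tRNA synthetase Hars (4.18 ± 0.20), Taok3 (4.10 ± 0.44), the G-quadruplex helicase Dhx36 (4.05 ± 0.49), Evi5 (4.01 ± 0.39), Cd28 (4.00 ± 0.42) and the kinesin Kif5b (3.74 ± 0.35). Before LPS, Tnf (-3.81 ± 0.18) and Fth1 (-3.72 ± 0.20) lay toward free mRNP and Nfkbia (1.39 ± 0.15) toward polysomes, while Il1b (0.17 ± 0.21) and Il6 (-0.12 ± 0.34) were not called. Actb stood at -0.83 ± 0.24, but was not called with median scaling (-0.42).

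Of 24 zinc-finger KRAB and Polycomb regulators 16 were higher in polysomes and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 8.5e-05, adjusted p = 0.17 with an estimated correlation). Of 32 proteasome subunits 18 were higher and 5 lower (19 and 5; camera adjusted p = 8.5e-05, adjusted p = 0.24 with an estimated correlation). Oxidative phosphorylation subunits lay toward free mRNP, with 12 of 74 higher and 45 lower (13 and 47; camera adjusted p = 0.00052, adjusted p = 0.59 with an estimated correlation). Cytokines had 0 of 28 higher and 14 lower (0 and 14; camera adjusted p = 0.0099, adjusted p = 0.22 with an estimated correlation). Cell cycle genes had 19 of 40 higher and 9 lower (19 and 9; camera adjusted p = 0.001, adjusted p = 0.22 with an estimated correlation). RNA-binding regulators had 14 of 30 higher and 6 lower (14 and 6; camera adjusted p = 0.0099, adjusted p = 0.29 with an estimated correlation). Markers of other cell types were faint and lay toward free mRNP where they were called, namely 6 of 8 for fibroblasts (camera adjusted p = 0.12). They were 4 of 7 for neutrophils and mast cells (camera adjusted p = 0.53), 1 of 5 each for B and T lymphocytes and epithelium (camera adjusted p = 0.7 for both) and 1 of 2 for erythroid cells. Counts over the list alone were the same, and 0 were higher in polysomes. In intact cells the median signal was 95.6 to 116.1 on free mRNP and 35.9 to 43.7 on polysome arrays. Whether this puts faint probe sets, also of cytokines, toward free mRNP was not tested. Of 3 replication-dependent histones 2 were higher and 0 lower (2 and 0). Nuclear noncoding RNAs had 1 of 10 higher and 5 lower (camera adjusted p = 0.51), including Pvt1 (-4.33 ± 0.27) and Malat1 (-3.19 ± 0.41). limma called 13993 probe sets, 5839 toward polysomes and 8154 toward free mRNP, around a median of -0.373 over all probe sets. With median scaling 60.6% of 12980 were toward polysomes. At 2 and 4 h, where both pools lie in one array set, 101 and 96 of 126 named results kept direction and call, 17 and 23 only the direction, and 8 and 7 turned. Nfkbia was among the last, at -0.43 and -0.55 in place of 1.39. In intact cells themselves array set and pool cannot be told apart.

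The change in free mRNP was also set against the change in total RNA, within array sets, in contrasts added after seeing the data. At 2 and 4 h the lower Actb 5' to 3' ratio of free mRNP goes with these contrasts too, against 0.765 and 0.715 in total RNA. At 1 h Nfkbia (1.48 ± 0.19, limma adjusted p = 1.7e-05) and Cxcl2 (2.41 ± 0.23) rose more in free mRNP than in total RNA, as did Wdr59 (2.31 ± 0.38). Nfkbia did so at 2 and 4 h (1.15 ± 0.19 and 1.49 ± 0.19). Mir155hg, the host transcript of microRNA 155, rose less in free mRNP at 2 h (-4.49 ± 0.52) and 4 h (-3.63 ± 0.52). So did Il12b at 2 h (-3.65 ± 0.58), Nsrp1 (-3.31 ± 0.67) and the interferon-stimulated genes Mx2 (-3.26 ± 0.59), Ifi207 (-4.26 ± 0.66) and Ifi204 (-3.26 ± 0.57). Tnf stood at -1.12 ± 0.22, -1.24 ± 0.22 and -0.88 ± 0.22, called at each time. At 1 and 4 h it was called neither with array weights (limma adjusted p = 0.099 and 0.11) nor with median scaling (-0.96 and -0.53). At 4 h it was also not called without array 2 of intact free mRNP, array 2 or 3 of intact total RNA, or array 1 or 2 of 4 h total RNA (limma adjusted p = 0.051, 0.067, 0.068, 0.063 and 0.053). Of interferon-stimulated genes, 0 of 35 rose and 14 fell (1 and 16 adjusted over the list alone) at 2 h (camera adjusted p = 0.00036, adjusted p = 0.39 with an estimated correlation). At 4 h, 1 rose and 8 fell (4 and 13, camera adjusted p = 0.00018, adjusted p = 0.26 with an estimated correlation). Of cytokines, 1 of 28 rose and 3 fell (1 and 7 adjusted over the list alone) at 1 h, on balance lower (camera adjusted p = 0.0011, adjusted p = 0.23 with an estimated correlation). Of NRF2 and antioxidant genes, 4 of 20 rose (4 adjusted over the list alone) at 4 h (camera adjusted p = 0.00022), with Mt2 (1.96 ± 0.36) the highest and 1 called with array weights. limma called 135, 1889 and 880 probe sets at 1, 2 and 4 h, 25, 713 and 206 with array weights, and 53, 918 and 230 with the compared groups alone. Rises made up 50.4%, 35.3% and 39.8% of calls, but 74.6%, 85.5% and 85% with median scaling and 67.1%, 52.8% and 58.5% with quantile normalization. Leaving out any total RNA array gave 37 to 74 calls at 1 h and 409 to 577 at 4 h, and any but 2 h array 2 gave 941 to 1178 at 2 h. Leaving out free mRNP intact array 1, 2 h array 1 or 4 h array 1 gave 330, 3050 and 1710.

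The authors' deposited tables list probe sets they called changed. Of the 640 listed as increased and 1849 as decreased in total RNA, 96.7% and 94.3% were called here in the same direction at 1 or more of the 3 times, counts from the same arrays and so no independent evidence. For polysomes the shares were 88.6% of 1257 and 84.5% of 1589, and for free mRNP 92.3% of 1221 and 100% of 67, all from the authors' deposited tables. Of the 119 and 454 probe sets in the authors' deposited tables of translationally raised and lowered transcripts, 78.2% and 70.5% were called in the shift in the same direction, 0 and 9 of them at 1 h.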

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

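The tests of the array sets, of fragmentation and of the signal range of Tnf, and the comparison of free mRNP with total RNA, were chosen only after the results were seen, while those of scaling, of transfer between pools and of total RNA levels were fixed before.

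Tnf changed more in polysomes than in free mRNP at 1 h (2.76 ± 0.25, limma adjusted p = 1.3e-07), and was marked because 2 pools differed under the same contrast. Tnf also rose more in polysomes than in total RNA, by 1.65 ± 0.22 (limma adjusted p = 8.8e-05), but this cannot speak against an upper limit of the signal, since at 1 h Tnf lay nearer to the highest signals on total RNA arrays (21720 to 23700 of 35580 to 38310) than on free mRNP arrays (49820 to 55480 of 126600 to 209200). Such a limit for the Tnf probe set stays open. The polysome arrays of intact and 1 h cells overlap in the spiked-in ratio (gap -0.13 between their ranges), which argues against the array set. A release of stored Tnf mRNA alone would not give the rises of Tnf also seen in free mRNP (2.24 ± 0.18) and total RNA (3.36 ± 0.09), and no other biological explanation was tested.

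Many probe sets were lower in polysomes at 2 and 4 h than in intact cells. The spiked-in ratio averaged 2.01 at these times against 0.869 in intact and 1 h polysomes (gap 0.856 between ranges). Of these falls 38.1% were followed by other probe sets of the gene. Within one set the share was 44.4% in free mRNP, 70.8% in polysomes from 2 to 4 h and 71.8% in total RNA at 4 h. Falls not followed already read lower than the gene's others in intact free mRNP against intact total RNA (median difference -1.09). A low share also arises in one set, and set goes with pool in the last value, so the array set stays open. Fragmentation would lower the Actb 5' to 3' ratio, which differed by 0.0394 between these polysome groups. A transfer to free mRNP stays open beside the array set. The falls had a median of 0.02 in free mRNP against total RNA at 4 h, above -0.2 for all probe sets.

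Falls outnumbered rises in free mRNP at 2 and 4 h. The authors' deposited tables have the opposite balance, with 1221 probe sets increased and 67 decreased in this pool. With quantile normalization falls made up 49.8% and 51.7% of calls in place of 69.3% and 67.9%, so the scaling may set the balance. The Actb 5' to 3' ratio was lower at 2 and 4 h than in intact cells (0.247 against 0.368, exact two-sided permutation p = 0.0476 over 84 splits), which is consistent with more fragmented RNA. Probe sets that fell at 4 h also lay lower in total RNA, with a median of -0.49 against -0.06 for all, which is what lower transcript levels would give. These 3 explanations do not exclude one another, and all stay open.

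Nfkbia changed by -1.75 in the shift at 1 h, rising more in free mRNP than in polysomes. An upper limit of its polysome signal was not tested and stays open. The shift was called for 47, 1952 and 1738 probe sets at 1, 2 and 4 h, each a difference between 2 pools. Free mRNP differed from total RNA in its response for 135, 1889 and 880. Outside the tested probe sets, a B1 repeat control averaged a signal of 104000 in free mRNP of intact cells, against 15300 in total RNA and 946 in polysomes.

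Other splits of the same arrays were counted. With 3 arrays against 3 there are 10, so a share under 0.05 cannot be had. All but the real one mix the 2 groups, which widens the spread. The highest other split gave 0 calls for each of the 4 total RNA contrasts, against 1786, 6891, 8005 and 6220, and 0 for polysomes at 2 and 4 h and for polysomes against free mRNP in intact cells, against 3433, 4852 and 13993. It gave 1 in polysomes at 1 h and from 2 to 4 h, against 455 and 570, and 346, 198 and 273 in free mRNP, against 857, 4361 and 4852. For the shift and for free mRNP against total RNA, 100 splits were drawn, the real one included. In the shift 11, 3 and 7 gave as many calls as the real 47, 1952 and 1738 at 1, 2 and 4 h (highest other 260, 2144 and 3449), and from 2 to 4 h all 100 gave at least the real 0 (highest other 1821). For free mRNP against total RNA 10, 4 and 9 gave as many as the real 135, 1889 and 880 (highest other 613, 2485 and 6725). The share was under 0.05 at 2 h alone. Some splits keep or exchange the groups of one pool and carry its response. The others mix the groups in both pools, which widens their spread. Neither kind shows what chance alone would give, so splits leave chance open for every contrast, at 2 h too.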

How the results depend on the processing

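The fits by pool, the array weights, polysomes against free mRNP at 2 or 4 h of LPS, the contrasts within array sets, the permutation within replicate numbers and, for single genes, the median of all their probe sets were chosen only after the data were seen. Among single-gene results that were called, 20506 of 22353 values under the alternatives kept direction and call, 1821 kept the direction without the call and 26 turned. Among those not called, 979 of 1063 kept direction and side, 14 became called and 70 turned. Where a value below differs from the reported one the cause was not tested, except that fewer arrays or another shared spread changes what a fit can call. Dim probe sets limit the data, since a signal near the background changes little after the offset of 32.

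Counts of calls moved most with the arrays that share a spread. One fit over all 36 arrays gave 417, 1751 and 3040 calls in total RNA at 1, 2 and 4 h, 1804 from 1 to 4 h. It gave 743 in polysomes at 1 h, 2444 and 6824 in free mRNP at 1 and 2 h, and 367, 3601 and 3359 in the shift at 1, 2 and 4 h. From 2 to 4 h it gave 1080 in polysomes and 1 in the shift. With array weights by RNA pool the counts were 1479, 6905 and 8471 in polysomes and 183, 1310 and 2076 in free mRNP at 1, 2 and 4 h. There were 29 in the shift at 1 h, 1999 in polysomes from 2 to 4 h, and 25, 713 and 206 for free mRNP against total RNA. The 12 arrays of a pool alone gave 1035, 6831 and 8261 in polysomes, 1678 from 2 to 4 h, and 264, 1928 and 2608 in free mRNP. The arrays of the compared groups alone gave 5872 in polysomes at 2 h, 367, 1708 and 2298 in free mRNP. They gave 17 in the shift at 1 h, 2198 in polysomes from 2 to 4 h, and 53, 918 and 230 for free mRNP against total RNA. eBayes without the trend gave 1226 and 1144 in the shift at 2 and 4 h and 353 in polysomes from 2 to 4 h. An offset of 100 gave 2 in the shift from 2 to 4 h. With an estimated correlation 59 of the 127 gene list calls of the planned contrasts remained. Quantile normalization called 92 lists, 81 of them among the 127, and all probe sets of a gene 144, 110 of them among the 127.

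Scaling moved 3 counts of calls by over 1.5 times, turned the balance of rises and falls in the contrasts where other shares are given above, and turned some small values. Quantile normalization gave 2853 calls in free mRNP at 2 h. It put Fth1 at -0.01 in total RNA at 2 h, at -0.17 in the shift at 1 h, and at 0.06, 0.15 and 0.18 in free mRNP against total RNA at 1, 2 and 4 h. Actb became 0 in total RNA from 1 to 4 h, 0, -0.05 and -0.03 in polysomes at 1, 2 and 4 h. It became -0.13 and -0.09 in the shift at 1 h and from 2 to 4 h, and 0.12 in free mRNP against total RNA at 1 h. Nfkbia became -0.08 in total RNA from 1 to 4 h and 0 in polysomes from 2 to 4 h, and Il6 0.01 in polysomes against free mRNP of intact cells. Scaling to the median of probe sets that pass the filter gave 145 calls in the shift and 59 for free mRNP against total RNA at 1 h. It put Fth1 at 0.06 in free mRNP at 2 h, -0.16 in the shift at 1 h and 0.02 in free mRNP against total RNA at 2 h. It put Actb at 0.03 in free mRNP at 4 h, -0.25 in the shift at 1 h, 0 from 2 to 4 h and 0.07 in free mRNP against total RNA at 1 h. Il6 became 0.11 in intact cells and Il1b 0.1 in free mRNP against total RNA at 2 h. With no offset and a floor of 16, Il1b became -0.01 in free mRNP against total RNA at 4 h.

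With total RNA in place of free mRNP the shift had 8, 977 and 1032 calls at 1, 2 and 4 h. At 1 h Fth1 turned to -0.4, Actb to -0.05, Il1b to -0.49 and Slfn2 to -0.73. At 2 h Actb turned to -0.23, Il6 to 0.21, Cxcl1 to -0.13, Oasl1 to -0.07, Psma1 to 0.2, Psma3 to 0.01 and Scarb2 to 0.19. At 4 h Actb turned to -0.03, Il6 to 0.27, Trim30a to -0.14, Adgre1 to -0.65, Hspa8 to -0.03, Scarb2 to 0.16, Scd2 to -0.31 and H1f2 to 0.87. From 2 to 4 h Tnf turned to 0.31, Nfkbia to 0.22, Il1b to 0.12 and Il6 to 0.06, none of them called in either setting. Polysomes against free mRNP at 2 h of LPS in place of intact cells gave Nfkbia -0.43, Il1b -0.35, Oasl1 0.64, Sesn2 0.01, Sec11c -0.38, Ccne2 -0.01, Zfp326 -0.32 and Col1a2 0. At 4 h they gave Nfkbia -0.55, Il1b -0.59, Sec11c -0.23, Ccne2 -0.68, H2bc21 -0.59, H1f2 0 and Dcn 0.26.

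Leaving out each array in turn gave 1039 to 1628 calls in total RNA at 1 h, 286 to 460 in polysomes at 1 h, 553 to 1102 in free mRNP at 1 h. It gave 22 to 66, 1236 to 2528 and 1073 to 2208 in the shift at 1, 2 and 4 h. The ranges were 266 to 472 in polysomes and 0 to 2 in the shift from 2 to 4 h, and 37 to 330, 941 to 3050 and 409 to 1710 for free mRNP against total RNA. It also turned values that were not called. Actb ranged over 0 to 0.21 in total RNA from 1 to 4 h, -0.08 to 0.24 in polysomes and -0.24 to 0.22 in free mRNP at 1 h. It ranged over -0.14 to 0.33 in the shift at 1 h, -0.09 to 0.15 in polysomes and -0.21 to 0.33 in the shift from 2 to 4 h, and -0.38 to 0.08 in free mRNP against total RNA at 1 h. Nfkbia ranged over -0.03 to 0.09 in total RNA from 1 to 4 h and -0.1 to 0.11 in polysomes from 2 to 4 h. Fth1 ranged over -0.06 to 0.31 in the shift at 1 h, Tnf over -0.2 to 0.1 in the shift from 2 to 4 h. Il6 ranged over -0.64 to 0.09 in the shift at 2 h and -0.44 to 0.29 in intact cells, and Il1b over -0.01 to 0.31 in intact cells and -0.09 to 0.24 in free mRNP against total RNA at 4 h.

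The labels do not say what a replicate number shares, and the rule for pairing was not met. Over 34 pairs of groups the median correlation of deviations between same-numbered arrays was 0.0132, 0 pairs of groups had every correlation over 0.1, and in 7 every array correlated best with its own number. With the replicate number as a block the shift had 88 calls at 1 h and 1 from 2 to 4 h, and with the block taken by numbered pair of polysome and free mRNP arrays 78 at 1 h. Total RNA had 2519, 8171, 9253 and 7501 calls with the block, each within 1.5 times the reported count. Some controls did follow the numbers, as on free mRNP arrays the Actb 5' to 3' ratio was highest on array 1 and lowest on array 3 in each of the 4 groups, and in total RNA the B1 control was lowest on array 3 in each. With the number as a block, in a test chosen after the data were seen, the ratio of intact minus 2 and 4 h free mRNP arrays stayed at 0.121, with an exact two-sided permutation p = 0.037, the smallest that 27 splits allow, against 0.0476 without it.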

Other observations

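The list tests below were fixed before the data were examined, and none was chosen after a result was seen, while the array sets were found afterwards.

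Of the uORF and stress list, 12 of 27 rose and 2 fell (14 and 2 adjusted over the list alone) in polysomes at 2 h (camera adjusted p = 2.6e-07). In free mRNP 14 of 27 rose and 1 fell (15 and 2 adjusted over the list alone) at 4 h (camera adjusted p = 4.2e-10). In the shift at 2 h the list was not called, as 7 of 27 rose and 3 fell (8 and 6 adjusted over the list alone) (camera adjusted p = 0.77). Members that moved included the stress-induced Sesn2 (2.06 ± 0.51) and the transcription factor Atf5 (1.51 ± 0.38) toward polysomes. At 4 h Ifrd1, whose mRNA carries a uORF, lay toward free mRNP (-1.67 ± 0.32). Of RNA-binding regulators 6 of 30 rose and 3 fell (10 and 5 adjusted over the list alone) in the shift at 2 h (camera adjusted p = 0.77), among them the exonuclease Xrn1 (2.22 ± 0.51) and the stress granule protein Tia1 (2.01 ± 0.49) toward polysomes. Tob1, which recruits deadenylases, lay toward free mRNP at 4 h (-2.05 ± 0.44). Among cell cycle genes the mitotic kinesin Cenpe (1.99 ± 0.36) and Mki67 (1.36 ± 0.29) shifted toward polysomes at 4 h. Of that list 4 of 40 rose and 6 fell (4 and 6 adjusted over the list alone), with a median of 0.04 and a mean of -0.03 (camera adjusted p = 0.51). With total RNA in place of free mRNP limma did not call Sesn2 (0.37), Atf5 (0.92, nor without the trend), Tia1 (1.36), Ifrd1 (-0.71) or Mki67 (0.59), and the other probe sets of Cenpe had a median of -0.34. Array set and time cannot be told apart in these shifts, and the Actb 5' to 3' ratio of free mRNP was lower at both times (0.232 and 0.262 against 0.368).

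Of cholesterol genes in total RNA at 4 h 2 of 23 rose and 9 fell (2 and 9 adjusted over the list alone) (camera adjusted p = 0.14, adjusted p = 0.0062 over all probe sets). The lowest were the desaturase Scd2 (-1.05 ± 0.06) and the reductase Dhcr7 (-0.97 ± 0.11). NRF2 and antioxidant genes went both ways, as 4 of 19 rose and 6 fell (5 and 6 adjusted over the list alone), with a median of -0.15 and a mean of 0.06 (camera adjusted p = 0.55). Slc7a11 (2.48 ± 0.14) and Sod2 (1.94 ± 0.11) rose, and Osgin1 fell (-2.16 ± 0.24). Of endoplasmic reticulum chaperones 1 of 23 rose and 10 fell (1 and 10 adjusted over the list alone) (camera adjusted p = 0.34, adjusted p = 0.026 with quantile normalization). Of oxidative phosphorylation subunits 3 of 73 rose and 10 fell (1 and 6 adjusted over the list alone) (camera adjusted p = 0.79, adjusted p = 9.7e-05 with quantile normalization). The fibroblast list had 1 fall among 3 measured, that of the growth factor receptor Pdgfra (-2.15 ± 0.28).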
